A study of Homo sapiens with 4 samples.

How the data were processed

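RNA-seq libraries of MCF-7 cells from 4 conditions were analysed: siNT and siCTCF, each at 0 h and 3 h of estradiol, with 1 library per condition. Groups were taken from the labels. Total RNA was isolated with a column kit and libraries were made with a strand-specific kit; whether the counting used the strand is not given in the sources used here. Each file held 27026 lines of a gene symbol and an FPKM value and no other column. The FPKM values were made by the authors with TopHat and Cufflinks on hg19, per the submitters' processing notes, and their versions, options and gene annotation are not given in the sources used here. Values of the 613 symbols with more than 1 line (2371 lines) were summed, which gave 25268 symbols. No mitochondrially encoded gene was among them, so the fixed list of mitochondrial genes could not be measured.

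Differences were taken between log2 values with a pseudocount of 1 FPKM, and folds are the antilogs of these differences. Genes were compared when their mean over the 4 libraries was at least 1 FPKM, which kept 11921 genes and left out 11309. A further 2038 symbols of small RNAs, 52 of them with a mean of at least 1 FPKM, were left out because such RNAs are mostly lost in these libraries and their FPKM values are unstable. No scaling beyond that in the deposited FPKM values was applied. Sums of FPKM were 371, 373, 375 and 380 (in units of 1000 FPKM) in siNT 0 h, siCTCF 0 h, siNT 3 h and siCTCF 3 h, upper quartiles were 23.1, 23.1, 23.3 and 23.7 FPKM, and the 20 most abundant genes took 11.4, 10.4, 11.3 and 10.4% of the sums. Read numbers were not given in the sources used here. Ratios of depth were read from symbols between 0.001 and 0.1 FPKM, where few fragments set the value, as the most common ratio between libraries within 0.5%. The counting precision of a single gene cannot be given without read numbers.

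The comparisons were estradiol (3 h minus 0 h) in each siRNA arm, siCTCF minus siNT at each time, and the difference of the estradiol responses of the arms. With 1 library per condition no p value was computed for them, and genes were counted by size: at least 2-fold in a single pair of libraries, or at least 1.5-fold in the same direction in both pairs. The number that independent lists would share was computed from the counts of each pair. The share of responsive genes with the larger response in the siCTCF arm was given with a Wilson interval, and its median difference with a bootstrap interval over genes from 10000 draws. Of 26 gene lists, 25 had measured members. Each list's median difference was set against 10000 random lists with the same number of genes from each of 20 bins of mean expression. The comparisons, size rules, gene lists, named genes and most alternatives were chosen before the data were examined.

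The genes named in the text were chosen by rule. For estradiol and for siCTCF they were the 10 highest and 10 lowest by the mean of the pairs among genes past 1.5-fold in the same direction in both, and for the difference of responses up to 8 in each direction past 2-fold. A set of 12 genes was always given (CTCF, ESR1, GREB1, TFF1, PGR, MYC, CXCL12, XBP1, CCND1, EGR3, RARA and NRIP1), which made 61 genes in all. From each fixed list at most 4 members were named by rank, the 2 highest and 2 lowest by mean difference.

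Alternatives were a pseudocount of 0.1 or 5, no filter or a filter at a mean of 5 FPKM, upper quartile and median ratio scaling, the highest line per symbol in place of the sum, stricter and looser fold rules, genes chosen in a single arm, and an additive limma model of siRNA and time with Benjamini-Hochberg adjustment at 0.05. That model had 1 residual degree of freedom, which takes the difference of responses as error, and a prior of 2.73 degrees of freedom. Added after the data were seen were leaving out genes listed under 0.01 FPKM in a library, removing a lowess trend on GC content, and dividing each arm by its SD over genes.

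For words in 3' UTRs, the 3' UTR of the longest protein-coding transcript per gene in GENCODE release 29 was used where it had at least 50 bases. Every word of 7 bases was compared with its frequency in genes of like 3' UTR length and GC content, and the highest score was set against those of 500 random lists. Neighbours were adjacent expressed genes in the order of their start positions in a RefSeq gene list. GENCODE release 29 is on another genome build than hg19, so only gene names and transcript sequences were used from it. RefSeq gave only gene order and older gene names.

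The steps were tested on simulated data in which known differences were planted. For estradiol, the 1.5-fold rule in both pairs passed 99.4% of genes planted at 2-fold, 0.299% of those planted at 1.3-fold and 0 of 58605 unchanged genes. For siCTCF it passed 98.5% of genes planted at 2-fold and 0 of 58605 unchanged genes, and the additive limma model passed 40.3% of genes planted at 1.3-fold and 4 of 11721 unchanged genes. In the same comparison 11 of 200 unchanged lists (5.5%) and 200 of 200 lists shifted by 0.3 lay outside the central 95% of random lists, and a planted 3' UTR word and planted neighbour pairs were found, with none found where none was planted. For the 1.5-fold rule, counted over 5 runs together, and for limma, noise was drawn independently for each library and without regard to expression level. It was drawn from the differences of responses, with those past 2-fold cut to 2-fold, so larger errors of single libraries could not arise. Genes with the lowest means were not planted. Differences between cultures shared by both libraries of an siRNA could not arise, so the passes of unchanged genes do not bear on them. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.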

Results

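The transcriptome of MCF-7 cells, an oestrogen receptor-positive luminal breast cancer line, was measured by RNA-seq after knockdown of CTCF and exposure to estradiol, the main natural ligand of the receptor. CTCF is a zinc finger protein that binds insulator sites and anchors chromatin loops together with cohesin. Cells were kept without hormone for 72 h in medium with 5% charcoal-stripped serum. They received 40 nM of an siRNA against CTCF (siCTCF) or of a non-targeting control siRNA from another vendor (siNT), and 100 nM estradiol for 0 h or 3 h. The question the series addresses is how the response of oestrogen receptor target genes depends on CTCF. There were 4 libraries, 1 for each combination of siRNA and time, so there were no replicates and no value carries a replicate error. Each library held FPKM values (fragment counts scaled by transcript length and library depth) for 25268 gene symbols. Their read totals were not given in the sources used here, and from the spacing of very low values the siCTCF libraries had 0.940 (0 h) and 0.858 (3 h) times, and the siNT 3 h library 0.998 times, the depth of the siNT 0 h library. Between 11810 and 11899 symbols reached 1 FPKM per library. All differences are of log2(FPKM + 1), called log2 differences, and all folds are of FPKM + 1, so both understate the change of genes with low values. They were computed for 11921 genes with a mean of at least 1 FPKM. "Higher" and "lower" are used for genes past 1.5-fold in the same direction in both pairs of libraries of a comparison, that is in both siRNA arms or at both times, unless a single pair is named.

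CTCF itself, the targeted gene, stood at 28.1 FPKM with siNT and 7.67 FPKM with siCTCF at 0 h, 3.35 times lower. At 3 h the levels were 26.5 and 7.37 FPKM, 3.28 times lower. The log2 differences were -1.75 and -1.71, so CTCF was low in both libraries labelled siCTCF. Estradiol left CTCF within 0.08 on the log2 scale in either arm, with differences of -0.08 in siNT and -0.05 in siCTCF. The paralogue CTCFL, a testis-restricted gene, did not exceed 0.0121 FPKM in any library.

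After 3 h of estradiol, 199 genes were higher and 53 lower in both siRNA arms. Among the highest were LINC01016, a long non-coding RNA, from 0.388 to 6.90 FPKM with siNT and from 7.0 to 31.3 FPKM with siCTCF, and EGR3, an early growth response transcription factor, from 0.966 to 6.81 FPKM and from 0.912 to 8.23 FPKM. RET, a receptor tyrosine kinase, went from 4.15 to 19.5 FPKM and from 15.4 to 61.9 FPKM, and GREB1, a growth regulator induced through the oestrogen receptor, from 10.9 to 42.9 FPKM and from 10.3 to 33.2 FPKM. The lowest was TNFRSF11B, the decoy receptor osteoprotegerin, from 15.9 to 5.38 FPKM with siNT and from 10.5 to 1.78 FPKM with siCTCF. RNF43, a ubiquitin ligase that removes Wnt receptors from the cell surface, went from 23.0 to 9.48 FPKM and from 10.1 to 1.70 FPKM.

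The other genes at the top of the estradiol comparison were RAPGEFL1 (log2 differences of 1.86 with siNT and 1.97 with siCTCF), the kinase SGK1 (1.89 and 1.74), SMTNL2 (1.35 and 2.65), VASN (1.25 and 2.75), the nucleotide receptor P2RY2 (1.25 and 2.05) and FAM25A (1.41 and 2.11), whose value is uncertain because near-identical gene copies share its reads. At the bottom stood the potassium channel KCNJ3 (-1.06 and -1.65), the sialyltransferase ST8SIA4 (-1.16 and -1.50), SLITRK6 (-0.91 and -1.61), the vesicle traffic GTPase RAB27B (-0.94 and -1.27), the transcription factor GRHL3 (-1.06 and -1.11), the antiproliferative gene BTG2 (-0.91 and -1.24), ENC1 (-0.83 and -1.28) and the read-through gene RPS10-NUDT3. RPS10-NUDT3 is uncertain, as its reads overlap those of both partner genes and its level in the siCTCF 3 h library was only 9.97e-05 FPKM. At 2-fold in single arms, 83 genes were higher and 6 lower with siNT, and 131 higher and 31 lower with siCTCF. Independent lists would share 10.7 higher and 1.22 lower genes where 199 and 53 were shared, and 3 genes passed 1.5-fold in opposite directions. Across genes, which are not independent replicates, the estradiol differences of the arms correlated with Pearson's r = 0.743.

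Well-known receptor targets gave a range of responses. PGR, the progesterone receptor, had log2 differences of 1.59 with siNT and 1.39 with siCTCF, MYC of 1.3 and 1.32, and RARA of 1.0 and 0.94. CCND1, cyclin D1, had 0.94 and 0.93. The chemokine CXCL12 had 1.87 and 1.10, and XBP1, a transcription factor of the secretory pathway, 1.53 and 0.98. TFF1, a secreted trefoil peptide, was abundant before estradiol (1137 FPKM with siNT, 840 FPKM with siCTCF) and differed by only 0.42 and 0.36, and the corepressor NRIP1 by 0.47 and 0.16. The receptor gene ESR1 itself differed by -0.34 and -0.37.

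Of 40 measured genes in a fixed list of estradiol-induced MCF-7 genes, 28 were higher in both arms, with list medians of 1.0 (siNT) and 0.93 (siCTCF), above all 10000 random lists matched on expression. EGR3 and RET led the list, and TFF3 (0.12 and -0.06) stood at its lower end beside NRIP1. In the list of estradiol-repressed genes, 4 of 15 were lower, among them CCNG2, an unconventional cyclin (-0.93 and -1.09), with medians of -0.44 and -0.31, below all random lists. KRT15 went the other way (0.59 and 0.54), short of the rule in the siCTCF arm. Of 30 ribosome biogenesis genes, 9 were higher, with medians of 0.47 and 0.39, above all random lists. RRS1, a nucleolar assembly factor, stood at 18.4 FPKM with siNT and 19.7 FPKM with siCTCF before estradiol and at 38.6 and 40.2 FPKM after it, and NOP16 differed by 0.97 and 0.75. Of 18 immediate early genes, 4 were higher (EGR3, FOS, MYC and KLF4), with FOS at 1.18 and 1.56 and list medians of 0.26 and 0.16. Of 25 p53 targets, PMAIP1 (1.04 and 1.18) and AEN (0.66 and 0.66) were higher, and BTG2 and TP53INP1 (-0.70 and -0.82) lower.

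**Figure D1:**
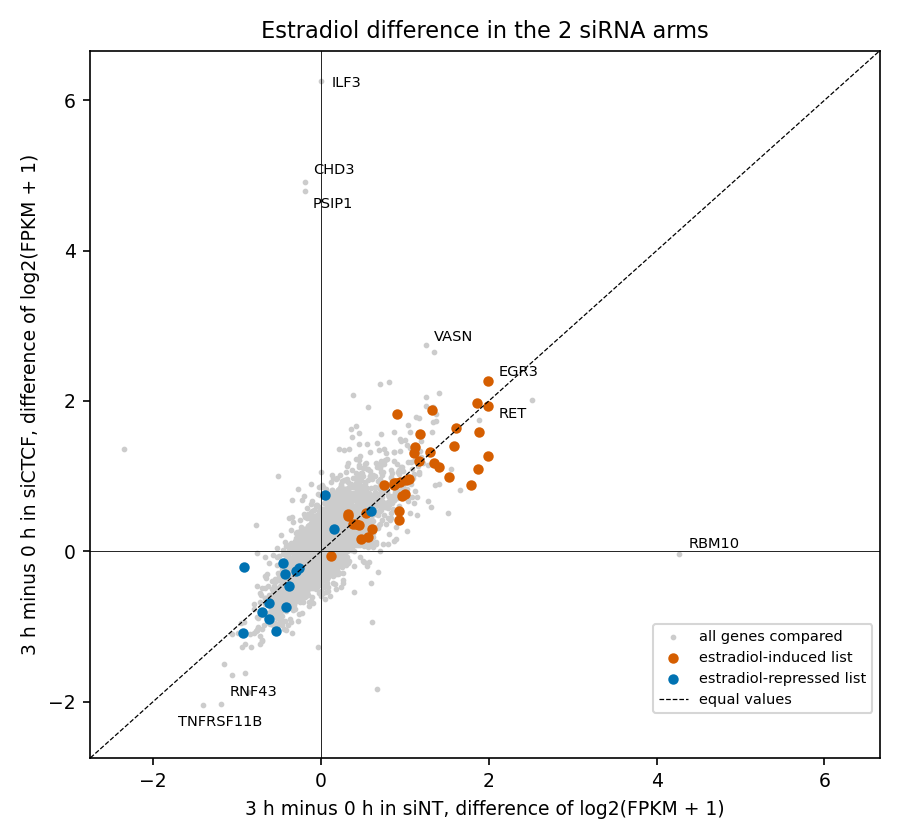
Log2 difference of log2(FPKM + 1) between 3 h and 0 h of estradiol in the siNT arm (x axis) and in the siCTCF arm (y axis), with 1 point for each of 11921 genes. Orange points are estradiol-induced and blue points estradiol-repressed list genes, the dashed line marks equal values, and among the genes far off it ILF3, CHD3, PSIP1 and RBM10 are listed at 0 FPKM, and SERF1A and PPAN-P2RY11 under 0.01 FPKM, in at least 1 library.

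Interferon-regulated genes had lower levels in the siCTCF libraries than in the siNT libraries. Without an untransfected library, reduced levels with siCTCF cannot be told from raised levels with siNT. All 30 measured genes of the fixed interferon-stimulated list were lower with siCTCF at both times, with list medians of -2.17 at 0 h and -2.24 at 3 h, below all random lists. OAS2, an oligoadenylate synthetase that senses double-stranded RNA, had 160 FPKM with siNT and 6.61 FPKM with siCTCF at 0 h, and 142 and 4.28 FPKM at 3 h, which is 21.2 and 27.1 times lower. IFIT3 went from 108 to 6.55 FPKM at 0 h and from 87.2 to 4.30 FPKM at 3 h. Antigen presentation genes were lower with siCTCF as well. PSMB8, an immunoproteasome subunit, went from 57.9 to 2.64 FPKM at 0 h, and HLA-B, a class I heavy chain whose reads can be shared with its HLA relatives, from 123 to 7.49 FPKM. B2M, the light chain of class I molecules, went from 2010 to 421 FPKM at 0 h and from 1929 to 384 FPKM at 3 h.

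Over all genes, 667 were higher and 599 lower with siCTCF at both times, where independent lists would share 66.7 and 48.6, and 2 went in opposite directions. At 2-fold in a single pair, 172 were higher and 245 lower at 0 h, and 226 and 264 at 3 h. Across genes the differences at the 2 times correlated with Pearson's r = 0.903, genes not being independent replicates. The remaining genes at the bottom were XAF1 (log2 differences of -4.10 at 0 h and -4.35 at 3 h), IFI44 (-3.99 and -4.13), UBE2L6, the conjugating enzyme of the ubiquitin-like ISG15 (-3.79 and -3.93), PSMB9, another immunoproteasome subunit (-3.73 and -3.76), CMPK2 (-3.59 and -3.58) and IFIT2 (-3.29 and -3.19), all known as interferon targets. At the top, PCP4, a small calmodulin-binding protein, had 36.9 FPKM with siNT and 550 FPKM with siCTCF at 0 h, and 69.5 and 619 FPKM at 3 h, 14.6 and 8.79 times higher. SUSD2, a membrane protein, went from 0.832 to 12.8 FPKM and from 0.873 to 15.9 FPKM. SYCE3, a protein of the meiotic synaptonemal complex, had log2 differences of 2.26 and 2.69, LINC01016 of 2.53 and 2.03, FDXACB1 of 1.97 and 1.96, DAPL1 of 1.69 and 2.23, GLIPR1L2 of 2.0 and 1.89 and FAM25A, with its near-identical copies, of 1.86 and 2.56. PXN-AS1 (2.15 and 2.09) and C1QTNF9B-AS1 (2.13 and 1.91) are antisense genes, and since the use of strand in the counting is not given, their reads cannot be separated from those of the genes opposite.

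Proliferation genes were higher with siCTCF. Of 30 G1/S and DNA replication genes, 21 were higher and none lower, with medians of 0.81 at 0 h and 0.80 at 3 h, above all random lists. TYMS, thymidylate synthase, had 17.7 FPKM with siNT and 43.4 FPKM with siCTCF at 0 h, and the origin licensing factor CDC6 7.64 and 18.7 FPKM. Of 30 G2/M genes, 20 were higher and none lower, with medians of 0.74 and 0.70, above all random lists. TOP2A, DNA topoisomerase II alpha, went from 33.6 to 90.4 FPKM and the mitotic kinase CDK1 from 32.7 to 77.9 FPKM at 0 h. CDKN1A, which encodes the cell cycle inhibitor p21, was the only lower one (-0.59 and -0.81) and FDXR the only higher one (0.59 and 0.68) of 25 p53 targets. The control siRNA came from another vendor and no further siRNA against CTCF was used. These and all other differences between siCTCF and siNT, also those of the estradiol response, therefore cannot be assigned to the loss of CTCF alone.

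Genes of chromatin architecture and of clusters that CTCF is known to organise moved in part. Of 16 measured clustered protocadherins, cell adhesion genes whose promoters bind CTCF, 8 were lower and none higher, with medians of -0.61 and -0.67, below all random lists. PCDHB8 had 5.11 FPKM with siNT and 0.717 FPKM with siCTCF at 0 h, and PCDHB16 6.93 and 2.45 FPKM, while PCDHA13 stood slightly above siNT (0.21 and 0.17). Members of the alpha and gamma clusters share exons, so their single values are uncertain. Of 9 imprinted genes, H19, a maternally expressed non-coding RNA controlled through CTCF sites, was the only one past the rule, with 2.05 FPKM in siNT and 7.08 FPKM in siCTCF cells at 0 h, and 3.47 and 13.5 FPKM at 3 h. The list medians were -0.11 and -0.06, within those of random lists. Of 22 genes of CTCF partners, cohesin and its regulators, 3 were higher, namely STAG1 (1.27 and 1.24), a cohesin subunit, and the cohesin regulators CDCA5 (0.97 and 1.12) and ESCO2 (0.85 and 0.87), with medians of 0.22 and 0.20. Of 21 nuclear matrix and lamina genes, TOP2A and the lamin gene LMNB1 (0.75 and 0.70) were higher, with medians of 0.19 and 0.25. None of 8 HOX genes passed the rule (medians of 0.16 and 0.27).

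**Figure D2:**
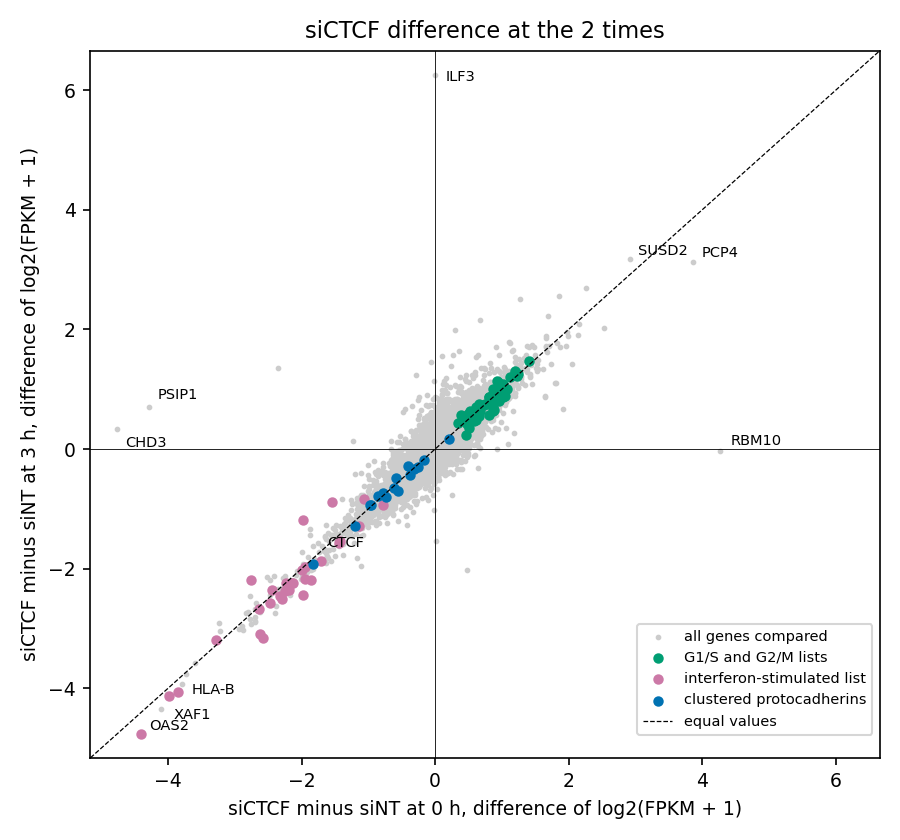
Log2 difference of log2(FPKM + 1) between siCTCF and siNT at 0 h (x axis) and at 3 h (y axis), with 1 point for each of 11921 genes. Pink interferon-stimulated genes lie at negative values on both axes, green G1/S and G2/M genes at positive values, and blue protocadherins mostly at negative ones; the dashed line marks equal values.

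The oestrogen receptor and its cofactors held single genes that moved. ESR1 had 64.4 FPKM with siNT and 134 FPKM with siCTCF at 0 h, and 50.7 and 104 FPKM at 3 h, 2.07 and 2.02 times higher. The epithelial transcription factor SPDEF was also higher (0.84 and 1.02) and TFAP2A lower (-0.66 and -0.78), the only ones of 23 in that list past the rule, with medians of -0.19 and -0.12. With estradiol, RARA and TFAP2C (0.61 and 0.65) of this list were higher, with medians of -0.01 (siNT) and 0.08 (siCTCF). Among estradiol-induced genes, 6 of 40 were higher with siCTCF and 2 lower, with medians of 0.20 and 0.13. RET had log2 differences of 1.67 and 1.62, CXCL12 of 1.64 and 0.86, and CCND1 of 0.64 and 0.62, while the growth factor gene AREG (-0.64 and -0.66) and WISP2 (-1.07 and -1.10) were lower. Of 15 estradiol-repressed genes, KRT15 was higher (0.98 and 0.93) and CCNG2 (-0.61 and -0.77) and CYP1A1 (-1.08 and -0.77) lower, with medians of -0.13 and -0.20. Genes higher with estradiol and higher with siCTCF numbered 24, where independent lists would share 11.1. For higher with estradiol and lower with siCTCF there were 4 (FAM189A2, RASGRP1, TGM2 and ULK1, named after their values were seen) where 10 would be shared. Lower with both were 13 against 2.66, and lower with estradiol but higher with siCTCF 0 against 2.97. The same 4 libraries enter both comparisons, so part of any difference from these values can come from shared libraries.

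With siCTCF, unfolded protein and amino acid stress genes had medians of -0.14 and -0.13, with HSP90B1 (-0.68 and -0.76) and SLC7A11 (-0.74 and -0.77) lower among 23. Immediate early genes had -0.17 and -0.24, with KLF6 (-0.63 and -0.72) lower among 18. Cholesterol synthesis genes had -0.15 and -0.24 with none of 19 past the rule, apoptosis regulators -0.14 and -0.14 with none of 21, and aminoacyl-tRNA synthetases -0.06 and -0.05 with none of 20. Ribosome biogenesis genes had 0.04 and -0.06 with none of 30 past the rule, p53 targets 0.07 and 0.02, and hypoxia and glycolysis genes 0.10 and 0.13, where HK2 (0.80 and 0.63) and NDRG1 (0.65 and 0.71) were higher and PFKFB3 (-0.76 and -0.64) lower among 18. Cytosolic ribosomal proteins had 0.15 and 0.17, with RPS14 (-0.59 and -0.63) lower among 51, and reference genes -0.11 and 0.01, with B2M lower among 17. Luminal markers had -0.04 and 0.01, with ESR1 higher and KRT7 (-0.72 and -0.67) lower among 16. Of markers of other cell types, 6 basal genes had -0.21 and -0.27, with KRT17 (-0.63 and -0.61) lower, 3 mesenchymal genes -0.04 and 0.17, and of the immune and endothelial list only 2 were measured, with medians of -0.84 and -0.95. These were CD68 (-0.03 and -0.05) and HLA-DRA, which went from 2.95 to 0.251 FPKM at 0 h beside the interferon-stimulated genes.

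With estradiol, the median of interferon-stimulated genes was -0.16 with siNT and -0.27 with siCTCF, below all random lists, with none of 30 past the rule. G1/S genes had medians of 0.09 and 0.10 and G2/M genes of -0.07 and -0.09, with none past the rule, and p53 targets of -0.09 and -0.09. Cholesterol synthesis genes had -0.05 and -0.13, aminoacyl-tRNA synthetases 0.11 and 0.09, cytosolic ribosomal proteins 0.04 and 0.05, reference genes 0.04 and 0.00, protocadherins -0.10 and -0.11, HOX genes -0.15 and -0.17, and imprinted genes 0.04 and 0.00. Cohesin and CTCF partner genes had -0.03 and -0.07, nuclear matrix genes 0.02 and 0.00, luminal markers 0.03 and 0.11, basal markers 0.05 and 0.01, mesenchymal markers 0.15 and 0.17, and immune and endothelial markers 0.21 and 0.11, none of these lists having a gene past the rule. Stress genes had -0.02 and -0.05, with XBP1 the only higher one. Hypoxia and glycolysis genes had 0.04 and 0.06, with EGLN3 (-0.62 and -0.95) lower, and apoptosis regulators -0.05 and -0.04, with PMAIP1 higher. Over 125 pairs of list and contrast, 48 medians lay outside the central 95% of random lists, where 6.25 would by chance. List members are regulated together, so these percentiles describe the libraries and are no test. KLF4, TFAP2C, ESCO2 and NDRG1 were named after their values were seen, to complete short counts.

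**Figure D3:**
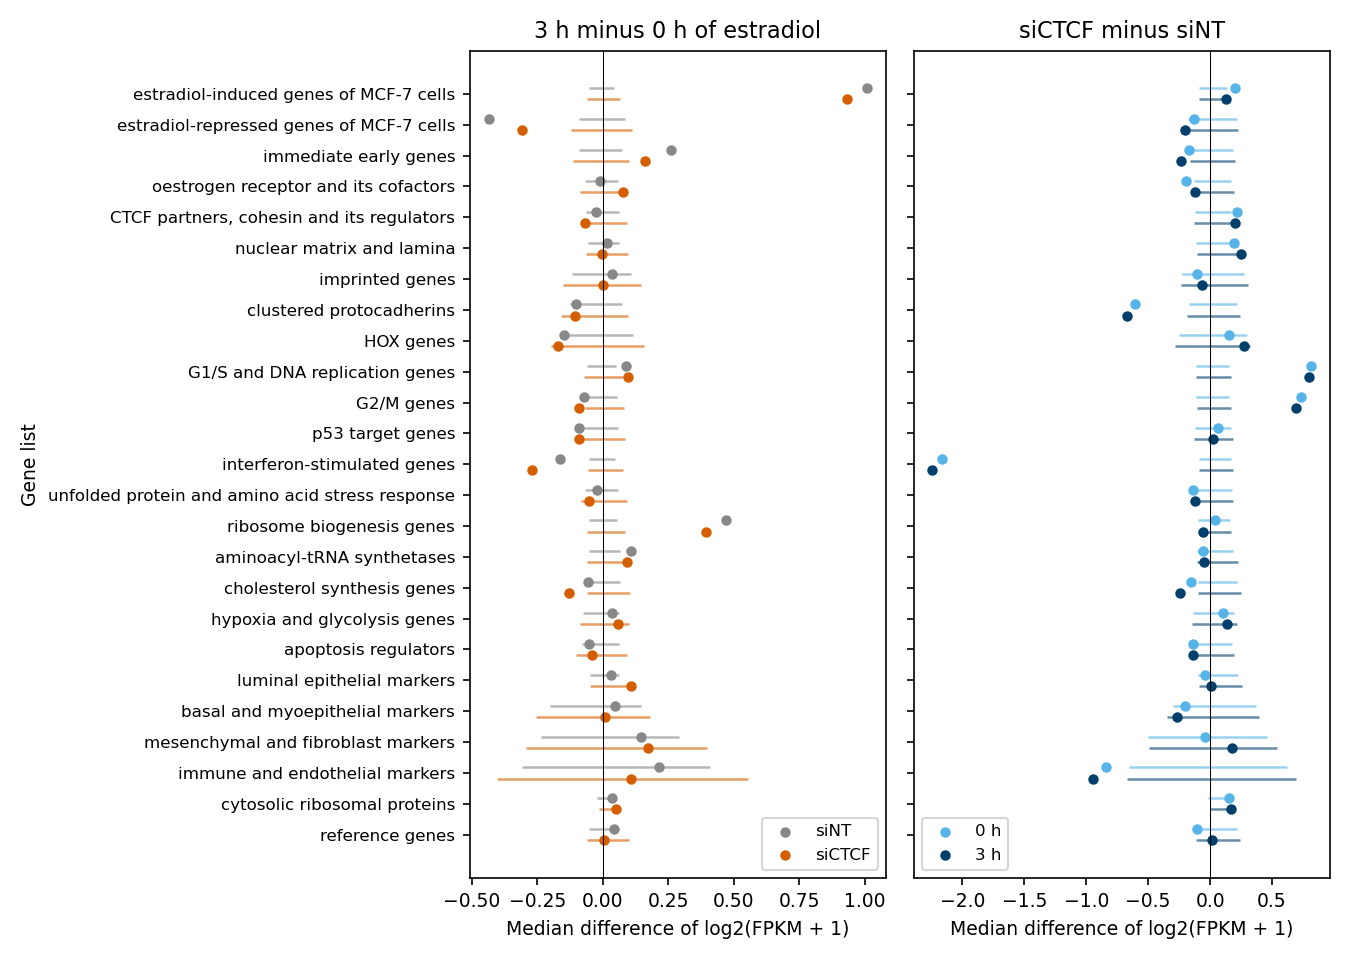
Median log2 difference of log2(FPKM + 1) of 25 fixed gene lists (points, x axis), for estradiol in each siRNA arm (left) and for siCTCF at each time (right), with horizontal lines for the central 95% of 10000 random lists of the same size and expression. Estradiol-induced and ribosome biogenesis genes stand to the right of the lines on the left, and on the right interferon-stimulated genes stand at -2.17 and -2.24 and the G1/S list at 0.81 and 0.80.

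The last comparison asked whether the estradiol response differed between the arms. The difference of responses (siCTCF arm minus siNT arm) passed 2-fold for 23 genes upward and 6 downward. VASN, a cell surface protein that binds TGF-beta, stood at 1.60 FPKM before and 5.16 FPKM after estradiol with siNT, and at 3.12 and 26.7 FPKM with siCTCF. The glycosyltransferase gene B3GNT3 had responses of 0.71 and 2.22, and the keratin KRT9 of 0.38 and 2.07. In the other direction, NPY1R, a neuropeptide Y receptor, went from 5.70 to 18.1 FPKM with siNT and from 13.3 to 19.3 FPKM with siCTCF, responses of 1.51 and 0.51. DDIT4L had -0.04 and -1.28, ENO1-AS1, an antisense gene, 0.60 and -0.42, and the uncharacterised LOC101929613 0.60 and -0.94.

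The 3 largest values upward and the largest downward came from genes listed at 0 in some libraries, for which no fold is given. ILF3 was listed at 0 in all libraries but siCTCF 3 h (75.6 FPKM). CHD3 and PSIP1 were listed at 0 in siCTCF 0 h alone (26.2, 22.8 and 29.2 FPKM, and 18.5, 16 and 26.7 FPKM, in siNT 0 h, siNT 3 h and siCTCF 3 h), and RBM10 in siNT 0 h alone (18.3, 18.2 and 17.8 FPKM in siCTCF 0 h, siNT 3 h and siCTCF 3 h). All 4 encode widely expressed nuclear proteins, and the files hold no status column that would tell a failed estimate from an absence of reads. SERF1A (responses of -2.35 and 1.36) has a near-identical copy, SERF1B. P2RY11 (-0.52 and 1.0) and PPAN-P2RY11 (0.67 and -1.83) are a gene and its read-through form that share reads.

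Among the 94 genes with a mean estradiol response of at least 2-fold upward, 65 had the larger response in the siCTCF arm (69.1%, Wilson 95% interval 59.2 to 77.6), with a median difference of 0.23 (95% bootstrap interval over genes 0.10 to 0.37). Without genes listed under 0.01 FPKM in a library, 62 of 90 had the larger response in that arm (68.9%), with a median difference of 0.20. All 12 genes at least 2-fold downward had the larger response in that arm. In the fixed list of estradiol-induced genes, however, 16 of 40 did (40.0%, Wilson interval 26.3 to 55.4). Its median difference was -0.06 (interval -0.19 to 0.01), at percentile 0.43 of random lists. Its members spread more (SD 0.34) than all genes (SD 0.21), for which the random lists were not matched. Both intervals of the list include an even split or no difference, so it did not share the excess of the genes picked from these libraries. The intervals treat genes as independent and do not cover variation between cultures. Choosing higher genes in the siNT arm alone gave a share of 44.6%, and choosing them in the siCTCF arm alone gave 87.8%. Each choice favours its own arm by construction. Of the 6 lower genes chosen in the siNT arm, 5 (83.3%) still had the larger response in the siCTCF arm. The difference of responses of 5 further lists lay outside the central 95% of random lists. The medians were -0.12 for interferon-stimulated genes, below all random lists, -0.07 for ribosome biogenesis genes, -0.06 for stress genes and -0.05 for cholesterol synthesis genes, and 0.08 for luminal markers. The random lists were not matched on GC content, with which the difference of responses correlated across 8369 genes with a mean of at least 5 FPKM (Spearman's rho = 0.330, genes not being independent replicates), from a median of -0.05 in the lowest of 8 GC groups to 0.06 in the highest.

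**Figure D4:**
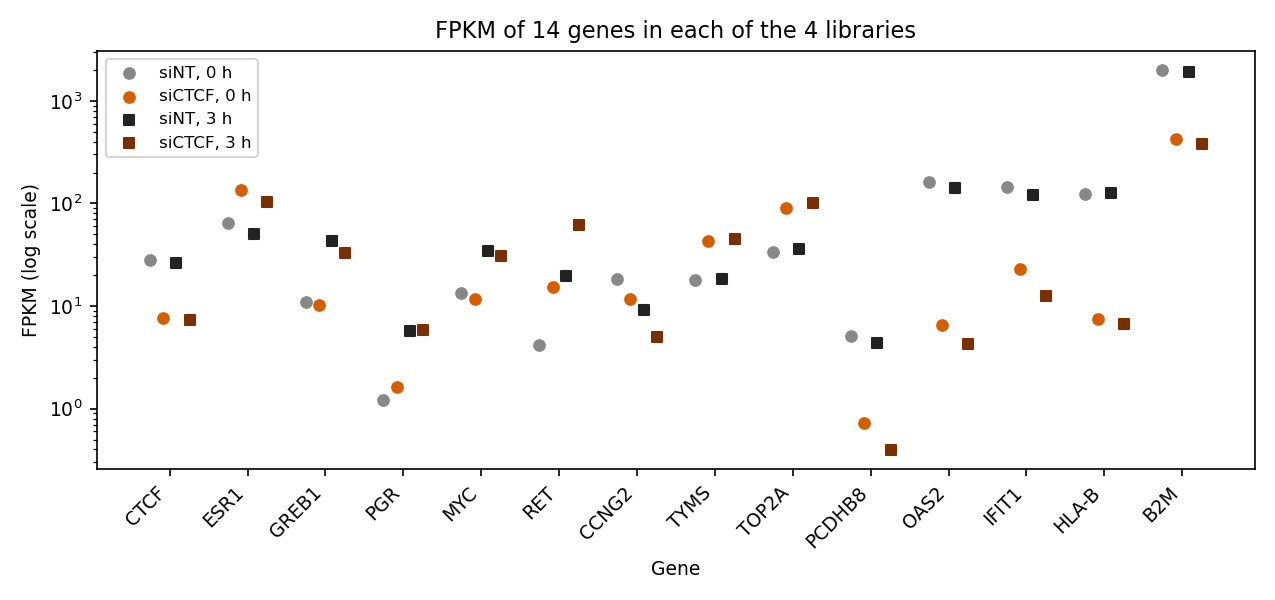
FPKM (y axis, log scale) of 14 genes in each of the 4 libraries, with circles for 0 h, squares for 3 h, grey or black for siNT and orange or brown for siCTCF, 1 point per library. CTCF lies at 28.1 and 26.5 FPKM with siNT and at 7.67 and 7.37 FPKM with siCTCF, and OAS2 at 160 and 142 FPKM with siNT and at 6.61 and 4.28 FPKM with siCTCF.

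The genes lower with siCTCF more often held certain short sequences in their 3' untranslated regions (3' UTRs). The word TTCCTCA stood in 169 of the 570 lower genes with an annotated 3' UTR, where 108 would be drawn at random among genes of like 3' UTR length and GC content, and ATTCCTC in 117 where 68.7 would. At least 1 of these words was present in 36.8% of the lower genes and in 24.8% of all 11020 genes searched. It was present in OAS2, IFI44, CMPK2 and IFIT2, and absent from XAF1, PSMB8, HLA-B, IFIT3, UBE2L6, PSMB9 and B2M. Among the other lower genes named, KLF6, CYP1A1, CDKN1A, PFKFB3, PCDHB16, HLA-DRA, RPS14, HSP90B1 and SLC7A11 held one, and PCDHB8, TFAP2A, AREG, WISP2, CCNG2, KRT7 and KRT17 did not.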

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

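The tests of the interferon pattern, of the fixed estradiol list and of the word ATTCCTC were chosen only after the result was seen, and the division of each arm by its SD was added after the data were seen.

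Single values were picked out because the effects of a gene had opposite signs in the arms or at the times; these differences were not tested. The estradiol response in the siCTCF arm minus that in the siNT arm was -1.55 for LOC101929613, -2.49 for PPAN-P2RY11 and 3.71 for SERF1A. The siCTCF difference at 3 h minus that at 0 h was 4.99 for PSIP1, a size set by the pseudocount as PSIP1 is listed at 0 in siCTCF 0 h, and 3.71 for SERF1A. The values of SERF1A and PPAN-P2RY11, listed under 0.01 FPKM in at least 1 library, also depend on the pseudocount. Among the small RNAs left out of the comparisons, SNORD22 was listed at 3824 FPKM in siCTCF 0 h and at 0 in the other 3 libraries.

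All 30 measured interferon-stimulated genes were lower with siCTCF at both times. Scaling or depth is argued against, as the median over the 2 times was -2.22 without further scaling and at most -2.23 under either of 2 scalings, and leukocytes in the siNT cultures are argued against by 6 leukocyte transcripts at no more than 0.423 FPKM. Transcripts of interferons themselves were lower too, with a median of -2.10 over IFNB1, IFNL1 and the near-identical IFNL2 and IFNL3. An interferon response of the siNT cells to their transfected siRNA, which came from another vendor than the siRNA against CTCF, therefore cannot be told apart from an effect of the loss of CTCF, since there was no untransfected library and no second siRNA. An effect of CTCF on these genes stays open as a biological hypothesis.

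Of 94 genes at least 2-fold higher with estradiol by the mean of the arms, 69.1% had the larger response in the siCTCF arm. Leaving out genes listed under 0.01 FPKM in a library kept 90 of the 94, of which 62 (68.9%) had the larger response in that arm. A GC content trend as the whole cause is argued against. Over these 90 genes, all with GC values, the median difference was 0.20 before and 0.19 after removal of the trend (bootstrap interval 0.09 to 0.31). A larger response of estradiol-induced genes in general is argued against by the fixed list, whose median difference was -0.0599 (interval -0.19 to 0.01). Choosing genes by the mean of arms of unequal spread (SD over genes 0.23 and 0.30) stays open as a candidate explanation: with each arm divided by its SD, the share was 38.7% (Wilson interval 29.4 to 48.9), although this division would also remove a true general increase. An effect of CTCF on single genes such as VASN stays open and was not tested.

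Genes lower with siCTCF held TTCCTCA in their 3' UTRs more often than matched genes (z = 7.27; the highest word of random lists had a median of 4.24, and 5.19 at the upper end of its central 95%), as siRNA seed pairing would give, while genes higher with siCTCF showed no such word (4.06 against a median of 4.31). A test set beforehand, that the 8-base word joining TTCCTCA and ATTCCTC stands in CTCF, came out against these words matching the seed of the guide strand (0 times). It was too strict in that the base opposite the guide's position 1 need not pair. It searched the sense direction only, so it does not bear on the other strand of the siRNA. The reverse complement of TTCCTCA stood in CTCF 2 times, which was not tested further. ATTCCTC stood in CTCF once in the sense direction, but it was picked as the only 1 of 4 7-base words looked up (0.243 expected by chance for each; 3 stood there as the reverse complement), so its presence is no evidence; tested afterwards, genes with ATTCCTC in their 3' UTR that missed the 1.5-fold rule had a median of -0.0495 at 0 h (random lists -0.01 to 0.03) and -0.0506 at 3 h, and with only the lower genes left out it was -0.0396 and -0.0420. The same test of TTCCTCA, which stood 0 times in CTCF in the sense direction, gave -0.0474 and -0.0441. These words share the 6 bases TTCCTC, and 486 of the genes searched hold them joined. TTCCTCA is therefore no independent control, and its result cannot tell which word the shift belongs to. The 27 genes with the 8-base word more than once had -0.0682 and -0.0648, within random lists (percentiles 17.4 and 23.1). The 486 genes with it at least once had -0.0911 and -0.104, below all random lists. They include 54 of the lower genes in which the words were found, so this is no separate support. The 27 genes are too few to tell whether more sites go with a larger difference. From the enrichment and the medians of genes missing the rule, an off-target effect of an siRNA on part of the lower genes may be present. However, the siRNA sequence was not given, nothing ties the words to it, and 360 of the 570 lower genes searched held neither word. Of the interferon-stimulated genes 12 of 30 held one, and of the protocadherins 1 of 16, and an effect of the loss of CTCF stays open for all of them.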

How the results depend on the processing

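The alternatives that left out genes listed under 0.01 FPKM, removed a GC content trend or divided each arm by its SD, and the tests on them, were chosen only after the result was seen. Counts at 2-fold are given in the order estradiol in siNT, estradiol in siCTCF, siCTCF at 0 h, siCTCF at 3 h and difference of responses, with 89, 162, 417, 490 and 29 genes as reported, followed by the counts at 1.5-fold in both pairs for estradiol (252) and siCTCF (1266). With a pseudocount of 0.1 they were 152, 293, 693, 814 and 64, and 401 for estradiol in both arms. With a pseudocount of 5 they were 23, 61, 163, 192 and 8, and 101 and 558. A smaller pseudocount counts more genes with low values by construction. With a filter at a mean of 5 FPKM, which compares fewer genes, siCTCF at 0 h gave 277, at 3 h 315 and the difference 13. At 3-fold the counts were 14, 37, 134, 135 and 7, and 7 and 112; at 1.5-fold 334, 690, 1543, 1771 and 176; and at 2-fold in both pairs 58 and 344, as stricter and looser rules must give. The split between higher and lower genes also moved: with a pseudocount of 5, 28.8% of the siCTCF genes at 0 h were higher against 41.2%, and with 0.1, 68.8% of the genes in the difference against 79.3%; the cause was not tested.

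The additive limma model called 826 genes for estradiol (516 higher, 310 lower; 3926 at an unadjusted p under 0.05), with 236 of the 252 among them, and 6113 for siCTCF (3255 and 2858; 7150 unadjusted), with all 1266. It takes the difference of responses as its error, so its calls rest on 1 residual degree of freedom. A difference between cultures or reagents that both libraries of an siRNA share counts as signal in this model. Its siCTCF calls therefore do not allow for variation between cultures and do not show an effect of CTCF. The share of genes higher with estradiol that had the larger response in the siCTCF arm (69.1%) was 44.6% for genes chosen in the siNT arm (37 against 46 genes) and 87.8% for genes chosen in the siCTCF arm; each choice favours its arm by construction. For genes lower with estradiol (100% as reported) the same choices gave 83.3% (5 of 6 genes) and 100%. With each arm divided by its SD it was 38.7%, and 75% for genes lower with estradiol; the cause was not tested. Of the values of these counts and shares under all alternatives, 67 stayed within their bounds, 34 moved and 2 changed direction. Of the values of single genes and lists, 436 stayed and 74 moved. Their bounds were fixed distances on the log2 scale, wider for genes than for lists. A change of direction was looked for only in single genes and in lists outside random lists, and none was found there. The number of lists outside random lists was 48, 49, 48 and 48 as reported, with a pseudocount of 0.1 and under the scalings, and 43 of 115 pairs with a filter at 5 FPKM. CTCF was lower with siCTCF under both scalings. Replicates could not be paired because there was 1 library per group. Pairing by time and by arm is what the additive limma model does, as it compares the siRNAs within times and the times within arms. Leaving out a library would remove a group. Depth was not given, so how far it limits genes with low values is unknown.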

Other observations

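The tests of the interferon, antigen presentation, chemokine, receptor and histone groups were chosen only after the result was seen; the count of neighbouring pairs with siCTCF was set before its result, and the counts without list genes and for estradiol were added to it. Interferon transcripts were present in the siNT cells and lower with siCTCF: IFNB1, interferon beta, stood at 5.33 FPKM with siNT and 0.303 FPKM with siCTCF at 0 h, and IFNL1, interferon lambda, at 9.89 and 0.938 FPKM. All 14 genes of a class I antigen presentation group were lower at both times, with medians of -2.73 and -2.70, and HLA-A had 183 and 26.1 FPKM at 0 h. Of 3 interferon-regulated chemokines, CCL5 (11.4 and 1.42 FPKM at 0 h) and CXCL10 (0.993 and 0.168 FPKM) passed the rule and CXCL11 (0.608 and 0.156 FPKM) did not, the latter pair with means under the filter of 1 FPKM. None of 5 interferon receptor genes passed the rule, with IFNLR1 among them at no more than 0.434 FPKM and so also under the filter. Among 51 histone genes the median was -0.41 and 11 were lower; histone transcripts mostly lack the poly(A) tail, so their values depend on the RNA selection.

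A hypothesis was that genes next to each other differ together with siCTCF, as loss of domain borders may give. Adjacent expressed genes with unlike symbols that passed the rule in the same direction made 91 pairs, where random lists of like expression gave a median of 62 (47 to 77). Without the genes of the fixed lists there were 73 against 51 (37 to 65), of which the higher genes' 37 pairs lay within those of random lists (18.0 to 38) and only the lower genes' 36 lay outside (14 to 33). Antigen presentation neighbours such as TAP2 with PSMB8 and TAP1 with PSMB9, which are in no fixed list, are still among the latter. Pairs included LINC01016 with GRM4, H19 with ASCL2 and CCND1 with MYEOV among higher genes, and CMPK2 with RSAD2 and PSMB8 with TAP2 among lower ones. Estradiol gave 12 pairs against 3 (0 to 8), so the pairing is not particular to siCTCF, and shared enhancers, gene clusters of common function or reads running into the next gene may give it as well.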
